A study of Mus musculus with 9 samples.

How the data were processed

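Poly(A)-selected, stranded RNA-seq libraries (TruSeq) were made from the mouse tumour lines 482N1, B16F10-BrM and E0771-BrM in culture, with 3 libraries per line (A, B and C). The deposited table holds raw read counts per gene symbol, made by the authors from sequence reads. Per the labels, the authors used FastQC, TopHat2 2.0.10, Bowtie 1.0.0, SAMtools 0.1.19 and Cufflinks 2.2.1 with the mouse build GRCm39. The labels name neither the tool that counted reads, nor the annotation, nor how the genes in the table were selected. Of 11046 genes in the table, 10304 had counts in every library, and no gene had a third-highest count below 8. Markers such as Tyr, Mlana, Sox10, Nkx2-1, Epcam and Cdh1 are absent from the table and are not analysed here, and absence from it was not read as lack of expression. Gene symbols were matched to a RefSeq gene list of an earlier build for gene order only (10783 matched), and no coordinates are given.

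The comparisons, tests, gene lists, named-gene rule and the first set of alternatives were fixed before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which removed 9 and left 11037, library sizes were scaled by TMM, and a model with 1 coefficient per line was fitted over all 9 libraries with robust quasi-likelihood dispersions. The common dispersion was 0.0059. Lines were compared in pairs by quasi-likelihood F tests, 2-sided, and over all 3 lines by the joint F test. A gene was called highest in a line where both of its pairwise comparisons pointed up, with the larger of the 2 one-sided p-values. The p-values of genes were adjusted by the Benjamini-Hochberg method within each comparison, and those of gene lists over all comparisons together, with a threshold of 0.05. Log2 fold changes are model coefficients with SE, levels are TMM-normalised CPM with the SD of 3 libraries, and principal components used log2 CPM with a prior count of 2.

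For a gene with no count in the 3 libraries of a line, the fold is given as "at least", against a floor of 3 counts over the group. For a gene with 1 to 3 counts a ratio, where one is given, has a 95% interval from the counts. For other such genes only the counts or levels are given. Total counts of 7332390 to 9293348 per library set these floors. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Gene lists (22) were tested with camera in limma 3.58.1 where at least 5 members were measured (18 lists, 54 tests adjusted together), with a preset correlation of 0.01, and again with a correlation estimated per list. Of 26 called list results, 2 were still called with the estimated correlation. Both were of the epithelial list, of which 5 of 27 genes were measured. Of the melanocyte, lung and mammary lists, with 22 genes each, 7, 5 and 4 were measured. Of the cytokine list 17 of 38 genes were measured, and of the brain colonisation list 15 of 26. A list result, called or not, covers the measured members only. Counts of called members are given over all genes tested and, where they differ, adjusted over the list alone. The lists covered lineage (melanocyte, lung, mammary, epithelial, mesenchymal), neural functions (glutamate, GABA, presynaptic release, synapse organisers, channels, axon guidance, neuron and glia markers), immediate early genes, brain colonisation, cytokines, interferon response, cell cycle, amino acid stress, sterol synthesis, p53 targets, and myeloid and endothelial markers.

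Named genes were, per pairwise comparison, the 10 highest and 10 lowest by the ratio of mean CPM plus 1 among genes that passed the threshold and whose libraries did not overlap, without predicted genes. To these were added the 8 that most set each line apart, up to 4 called members per list and comparison by absolute log2 fold change, and fixed panels of tumour genes and sex chromosome genes. The text prints a selection of them, and Rn18s, neighbours of Egr1 and Trp53, the transcripts used for shares of the B16F10-BrM level and members of added families were chosen after the data were seen or for a check.

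Alternatives changed 1 choice at a time: DESeq2 size factors or upper-quartile factors in edgeR, DESeq2 1.42.0, limma-voom, no filter or a filter of 1 CPM in 3 libraries, the library letter as a block, each library left out, only the 2 lines compared, glmTreat against a 2-fold change, the estimated correlation, and fry. Removal of ribosomal RNA genes, and the use of only library B of 482N1 and of E0771-BrM, were added after the data were seen. In the latter, each lone library was assumed to vary like those of B16F10-BrM. The procedure was tested on simulated data in which 200 genes were changed in B16F10-BrM by 1 of 3 fold sizes and a further set was raised by 1.5-fold, of which 223 in all stayed among the 10997 genes fitted. Of the former, between B16F10-BrM and 482N1 it recovered 61.5% of those changed by 1.5-fold, 95.5% by 2-fold and 100% by 4-fold. It called 10 of 10774 unchanged genes. Most simulated genes were unchanged, whereas 73.7% to 78.1% of genes were called in the pairwise comparisons of the real data. The simulation therefore does not measure the rate of false calls or the scaling in the real data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.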

Results

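RNA from 3 mouse tumour cell lines grown in culture without treatment was profiled by poly(A)-selected, stranded RNA sequencing. The labels give 482N1 as a lung non-small-cell carcinoma line, B16F10-BrM as a BRAF-mutant melanoma line and E0771-BrM as a triple-negative breast cancer line, and BrM stands for brain metastatic. Each line had 3 libraries, called A, B and C, and the labels do not say whether these came from separate cultures. The SDs, SEs and adjusted p-values below measure variation between cultures only if they did. 482N1 and B16F10-BrM were grown in DMEM and E0771-BrM in RPMI 1640 with HEPES, so every difference between E0771-BrM and another line is also a difference of medium. The deposited table held 11046 genes. Total counts lay between 7332390 and 9293348 per library. Levels below are normalised CPM (library-size-scaled counts), given as mean ± SD of 3 libraries, and log2 fold changes are given ± SE.

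The libraries grouped by line. The first principal component held 52.6% of the variance and the second 44%. Spearman's rho across genes lay between 0.991 and 0.994 within lines, between 0.73 and 0.735 for B16F10-BrM with 482N1, between 0.759 and 0.768 for E0771-BrM with 482N1 and between 0.785 and 0.79 for E0771-BrM with B16F10-BrM. These correlations run across genes, which are not independent replicates. The 18S ribosomal RNA gene Rn18s took 12.3 ± 0.758% of counts in 482N1, 7.24 ± 0.797% in B16F10-BrM and 7.44 ± 0.809% in E0771-BrM (SD, n = 3). The 2 mitochondrial ribosomal RNAs took 4.09 ± 0.615%, 3.3 ± 0.385% and 1.8 ± 0.356% in the same order.

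**Figure D1:**
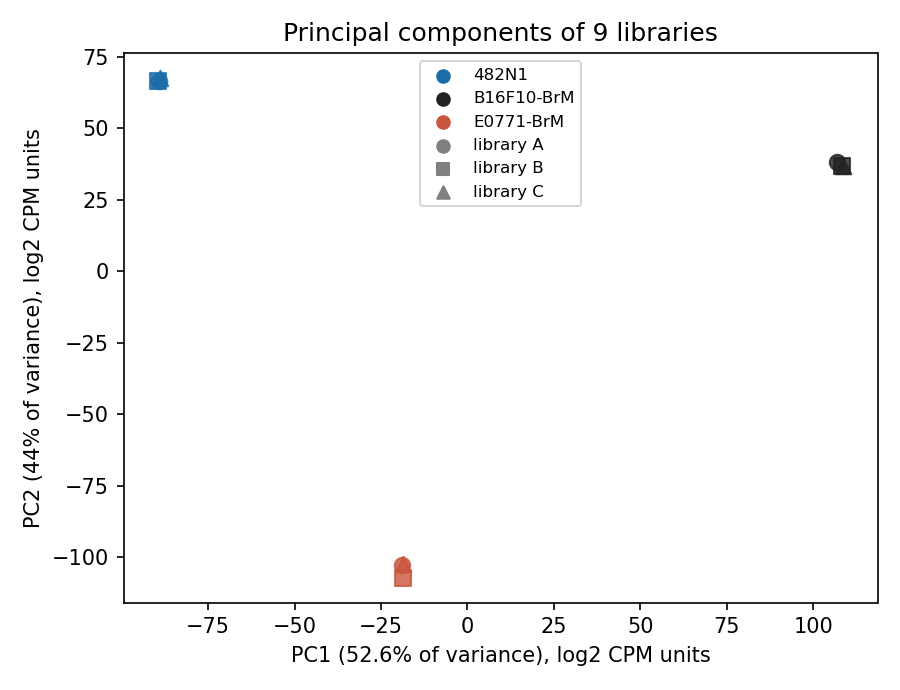
Scores of the 9 libraries on the first principal component (x axis, 52.6% of the variance) and the second (y axis, 44%), in log2 CPM units, with colour for the line and marker shape for libraries A, B and C. The 3 libraries of each line overlap or nearly overlap, and the lines lie far apart on both axes.

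The first comparison asked how the melanoma line differed from the lung line. Melanin-synthesis and melanosome genes were among those most raised in the melanoma line, and 4 of them ranked first by the ratio of mean CPM plus 1. Dct, the dopachrome tautomerase of melanin synthesis, had 17216 ± 425 CPM in B16F10-BrM and 12.9 ± 9.73 CPM in 482N1, a log2 fold change of 10.40 ± 0.92 (edgeR quasi-likelihood F test, Benjamini-Hochberg adjusted p = 3.97e-05). The melanosome matrix gene Pmel had 2164 ± 101 CPM against 1.24 ± 1.07, and Tyrp1, an enzyme of melanin synthesis, 2038 ± 41.7 against 1.92 ± 1.66. Gpnmb, a melanosome glycoprotein, had 2733 ± 258 against 1.61 ± 1.08, and Mitf, the transcription factor of the melanocyte lineage, 1029 ± 26.4 against 1.9 ± 1.05. All 7 measured genes of the melanocyte and pigmentation list were higher in B16F10-BrM, with a median log2 fold change of 10.07 (camera adjusted p = 2.7e-08; adjusted p = 0.0733 with an estimated correlation). Library B of 482N1 held 14 counts of Dct and libraries A and C 142 and 148. With only library B of 482N1 and of E0771-BrM, a setting chosen after the data were seen, the log2 fold change of Dct was 13.31 and the median of the melanocyte list 12.83 (range over the alternatives 9.46 to 12.83). Away from pigmentation, Syt4, a synaptotagmin of vesicle release, had 1180 ± 1.89 CPM in B16F10-BrM, with 6, 0 and 16 counts in the 482N1 libraries. Sox11, a transcription factor of neural development, had 465 ± 17.8 CPM against 0.883 ± 0.28, and Sirt5, a mitochondrial deacylase, 3662 ± 287 against 15 ± 1.03. The zinc finger gene Zfp575 had 600.3 ± 41.1 CPM against 7 counts.

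Epithelial genes were the mirror image. The keratin partners of simple epithelia, Krt18 and Krt8, had 4180 ± 223 and 3512 ± 132 CPM in 482N1. No count of Krt18 was found in the 3 B16F10-BrM libraries, so that it was at least 36400-fold higher in 482N1 against a floor of 3 counts over the group. Krt8 had 2 counts there, a ratio of 45900 (95% counting interval 12700 to 379000). The calcium-binding gene S100a6 had 13700 ± 56.5 CPM in 482N1 and 1.2 ± 0.411 in B16F10-BrM. The secreted chaperone clusterin, Clu, had 3446 ± 105 against 2.3 ± 0.977, a log2 fold change of -10.52 ± 0.13 (edgeR adjusted p = 1.49e-45). Wfdc2, Ankrd1, the annexin Anxa3, the thrombin receptor F2r and the matrix gene Fbln2 were also at 0 in every B16F10-BrM library and at least 5610-, 4970-, 4520-, 4080- and 3580-fold higher in 482N1. All 5 measured genes of the epithelial adhesion and keratin list were lower in B16F10-BrM, with a median of -13.08, or -10.15 with genes at 0 set to their bound and -11.15 with limma-voom (camera adjusted p = 2.98e-15; adjusted p = 0.00961 with an estimated correlation). Of 5 lung epithelium genes 4 were lower and 1 higher (median -4.10, camera adjusted p = 0.00378; adjusted p = 0.172 with an estimated correlation). The lung transcription factor genes Foxa1, at 0.534 ± 0.16 CPM against 40.3 ± 0.0966, and Etv5, at 2.76 ± 0.716 against 47.3 ± 5.27, were among the lower. All 4 measured genes of the mammary list, too few to test as a set, were lower in B16F10-BrM (Areg, Erbb2, Foxa1 and Gata3). Of 19 mesenchymal and matrix genes, 13 were lower in B16F10-BrM and 5 higher (median -3.59, camera adjusted p = 0.0305; adjusted p = 0.109 with an estimated correlation). Twist1, a transcription factor of mesenchymal fate, was at 0 in B16F10-BrM and at least 189-fold higher in 482N1, and collagen VI, Col6a1, at least 178-fold.

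The series title ties these lines to electrophysiological effects, and several neural lists bear on that. Only part of each list was measured: 24 of 50 axon guidance, 9 of 56 channel, 8 of 35 glutamate and 12 of 34 presynaptic genes. The same held for 12 of 49 synapse organiser, 7 of 20 neuron and glia and 2 of 25 GABA genes. Nothing is known here of the unmeasured members. Of 24 axon guidance and neurotrophic genes, 18 were lower in B16F10-BrM than in 482N1 and 6 higher (median -3.18, camera adjusted p = 0.00928; adjusted p = 0.0733 with an estimated correlation). The repulsive guidance cue Sema3a had 44 ± 5.53 CPM in 482N1 and 6 counts in the 3 B16F10-BrM libraries. Of 9 voltage-gated and potassium channel genes, 6 were lower and 2 higher (median -2.88, camera adjusted p = 0.0334; adjusted p = 0.125 with an estimated correlation). Kcnn4, a calcium-activated potassium channel, had 12.7 ± 1.33 CPM against 138 ± 13 (log2 fold change -3.44 ± 0.12, edgeR adjusted p = 3.38e-30). Cacna2d1, an auxiliary subunit of calcium channels, had 1 count against 994, a ratio of 1090 (95% counting interval 194 to 42900). The remaining neural lists were not called. The glutamate list had 1 gene higher and 6 lower of 8 (camera adjusted p = 0.196) and the presynaptic release list 4 higher and 7 lower of 12 (0.689), with Syt4 higher and the release factor Unc13a lower at 0.41 ± 0.248 against 23 ± 3.56 CPM. The synapse organiser list had 4 higher and 7 lower of 12 (camera adjusted p = 0.164) and the neuron and glia list 3 higher and 3 lower of 7 (0.319). Of the 2 measured GABA genes Aldh5a1 was higher and Gabbr1 lower.

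Immediate early genes were lower in B16F10-BrM in 21 of 25 cases and higher in 3 (median -2.68, camera adjusted p = 5.18e-10; adjusted p = 0.0557 with an estimated correlation). Egr1, the early growth response transcription factor, had 97.5 ± 3.24 CPM in 482N1 and no count in B16F10-BrM, at least 851-fold lower. Fosl1, a partner of Jun in AP-1, was at least 483-fold lower. Nr4a3, a nuclear receptor, was one of the 3 that went the other way, at least 278-fold higher in B16F10-BrM. Of 15 genes reported to favour brain colonisation, 13 were lower in B16F10-BrM and 2 higher (median -1.98, camera adjusted p = 4.19e-05; adjusted p = 0.093 with an estimated correlation). Angptl4, Ptgs2, which makes prostaglandins, and the gap junction gene Gja1 were at 0 in B16F10-BrM and at least 705-, 123- and 73.5-fold higher in 482N1. L1cam, an axonal adhesion gene, was higher in B16F10-BrM, with 11.7 ± 1.87 CPM against 8 counts. Of 17 cytokine and chemokine genes 10 were lower and 4 higher (median -2.69, camera adjusted p = 0.0139; adjusted p = 0.323 with an estimated correlation). Spp1, osteopontin, had 2.18 ± 0.0413 CPM against 870 ± 23.7, and the macrophage growth factor gene Il34 was at least 544-fold lower.

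Cell cycle genes were higher in B16F10-BrM in 33 of 36 cases and lower in 2 (median 1.21, camera adjusted p = 1.52e-10; adjusted p = 0.0557 with an estimated correlation). The mitotic kinase gene Plk1 had 130 ± 12.9 CPM against 3.23 ± 1.33 (log2 fold change 5.31 ± 0.14), the ribonucleotide reductase subunit Rrm2 162 ± 13 against 3.8 ± 0.61 (5.41 ± 0.13) and the replication licensing gene Cdc6 41.7 ± 6.02 against 3.27 ± 1.14 (3.65 ± 0.19). The other lists were not called. Interferon and antigen presentation genes were higher in 11 and lower in 8 of 24 (camera adjusted p = 0.278) and amino acid stress genes higher in 12 and lower in 8 of 25 (0.419; median 0.47, mean -0.03). Sterol and fatty acid genes were higher in 13 and lower in 9 of 30 (camera adjusted p = 0.369) and p53 targets higher in 13 and lower in 8 of 25 (0.251; median 0.52, mean -0.06). Of the marker pairs too small to test, both myeloid genes, Cd14 and Cd68, were lower in B16F10-BrM, and of the endothelial genes Egfl7 was higher and Flt1 lower.

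Across all genes, 8592 of 11037 tested (77.8%) differed between B16F10-BrM and 482N1 at an adjusted p below 0.05, 4190 higher and 4402 lower in B16F10-BrM. A fitted change of at least 2-fold was seen for 2086 of the higher and 2413 of the lower genes, and of at least 8-fold for 381 and 677. Of 18 lists tested, 10 were called, 2 higher and 8 lower, and the counts of members adjusted over the list alone equalled those over all genes in each list of this comparison. A test against a 2-fold change, glmTreat, called 3477 genes, and only the epithelial list of these 10 was called with an estimated correlation. With limma-voom the calls were lost of the lung list (camera adjusted p = 0.0506; range over the alternatives that used camera 0.00295 to 0.172), the mesenchymal list (0.148; 0.0175 to 0.148), whose median moved to -2.31, the channel list (0.0928; 0.0296 to 0.125) and the cytokine list (0.108; 0.0104 to 0.323). The mesenchymal, channel and cytokine calls were also lost with only library B of 482N1 (camera adjusted p = 0.0741, 0.0627 and 0.087), and the mesenchymal call without library A of B16F10-BrM (0.0515).

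The next comparison set the breast cancer line, in its own medium, against the lung line. Interferon-stimulated genes were higher in E0771-BrM. Rsad2, the antiviral enzyme viperin, had 466 ± 62 CPM in E0771-BrM and 0.128 ± 0.129 in 482N1, and Ifitm3, which restricts viral entry, 389 ± 30.4 against 0.462 ± 0.159 (log2 fold change 9.68 ± 0.17, edgeR quasi-likelihood adjusted p = 3.73e-42). Gbp7, a guanylate-binding gene, had 227 ± 27.5 against 0.789 ± 0.161 CPM. The ubiquitin-like modifier Isg15 had 79 ± 17.9 against 0.254 ± 0.227 and Ifit1 119 ± 23.4 against 0.508 ± 0.67. Of 24 interferon and antigen presentation genes 23 were higher in E0771-BrM and 1 lower (median 3.15, camera adjusted p = 1.63e-13; adjusted p = 0.0656 with an estimated correlation). Other genes with the largest differences were Hspb8, a small heat shock gene, with 382 ± 8.13 CPM against 5 counts in the 482N1 libraries, all in library A, and the matrix metalloproteinase Mmp3, with 319 ± 6.38 CPM against 4 counts. They also included the growth cone gene Gap43, with 381 ± 18.9 against 0.89 ± 0.912 CPM, and the actin-bundling gene Lcp1, with 310 ± 11.3 against 1.21 ± 0.0748 (7.98 ± 0.15). The collagen receptor Ddr2 and the secreted olfactomedin Olfm1 reached 185 ± 5.13 and 153 ± 6.56 CPM in E0771-BrM against 9 and 2 counts.

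Higher in 482N1 were Krt18, with 4180 ± 223 CPM against 9 counts in E0771-BrM, and Krt8, with 3512 ± 132 against 188 ± 18.7 CPM. The transcription factor genes Sox4 and Onecut2 had 999.9 ± 8.01 and 872 ± 47.5 CPM in 482N1 against 9 and 3 counts, and the adhesion gene Alcam 594 ± 34.6 CPM against 6 counts. Camk2n1, an inhibitor of calmodulin kinase II, had 556 ± 51.7 CPM against 4 counts, and fibronectin, Fn1, 520 ± 42.9 against 0.996 ± 0.386 CPM (log2 fold change -9.01 ± 0.15). Of 5 epithelial genes 4 were lower in E0771-BrM and the desmosomal plakophilin Pkp3 was higher, at 42.1 ± 2.62 against 2.73 ± 0.965 CPM (list median -2.42, camera adjusted p = 2.39e-07; adjusted p = 0.0371 with an estimated correlation). Of 5 lung epithelium genes 4 were lower and 1 higher (median -4.07, camera adjusted p = 0.00606; adjusted p = 0.205 with an estimated correlation). The surfactant lipid transporter Abca3 had 3 counts in E0771-BrM and 22.3 ± 1.41 CPM in 482N1, and Ctsh, a lysosomal protease, 2.45 ± 0.65 against 113 ± 12.3 CPM. All 4 mammary genes, Areg, Erbb2, Foxa1 and Gata3, were lower in the breast line than in the lung line, although the call of Gata3 was lost without library C of 482N1 (edgeR adjusted p = 0.0676) and with only library B of both lines (0.355; range over the alternatives 0.00818 to 0.355). Mesenchymal genes were higher in 11 and lower in 6 of 19 and not called (camera adjusted p = 0.584), and melanocyte genes higher in 3 and lower in 1 of 7 and not called (0.319; median 1.07, or 4.68 with only library B of both lines), with Mitf at 35.6 ± 2.69 against 1.9 ± 1.05 CPM.

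Synapse organiser and scaffold genes were lower in E0771-BrM in 11 of 12 cases and higher in 1 (median -1.32, camera adjusted p = 5.95e-04; adjusted p = 0.0557 with an estimated correlation). The synaptic adhesion gene Cadm1 had 0.63 ± 0.58 CPM against 372 ± 7.98 and the receptor phosphatase Ptprf 4.7 ± 0.634 against 139 ± 11 (log2 fold change -4.88 ± 0.15, edgeR adjusted p = 2.59e-28). Libraries A, B and C of E0771-BrM held 9, 0 and 6 counts of Cadm1. The gene that was higher was Il1rap, at 7.74 ± 1.08 against 0.805 ± 0.647. Of 24 axon guidance and neurotrophic genes 17 were lower and 6 higher (median -1.64, camera adjusted p = 0.0221; adjusted p = 0.0968 with an estimated correlation). The semaphorin Sema3e had 1 count in E0771-BrM and 1651 in 482N1, a ratio of 1670 (95% counting interval 299 to 66000). The axon repellent Slit2 had 0.535 ± 0.134 against 50.6 ± 6.95 CPM. Sema3a went the other way, at 131 ± 5.35 against 44 ± 5.53 CPM (log2 fold change 1.57 ± 0.10). Channel genes were higher in 3 and lower in 5 of 9 (camera adjusted p = 0.196). Among them the sodium channel gene Scn2a was at 0 in E0771-BrM and at least 65.1-fold higher in 482N1, Kcnn4 had 13.9 ± 2.67 against 138 ± 13 CPM, and the potassium channel gene Kcnh2 had 16.6 ± 1.26 CPM against 10 counts. Glutamate genes were higher in 3 and lower in 2 of 8 (camera adjusted p = 0.751; median 0.01, mean -0.50). Presynaptic genes were higher in 2 and lower in 6 of 12 (camera adjusted p = 0.2), or 1 and 6 adjusted over the list alone, and neuron and glia genes higher in 2 and lower in 4 of 7 (0.689; median -2.09, although the test pointed up). The GABA genes were again split, with Aldh5a1 higher and Gabbr1 lower.

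Cell cycle genes were higher in E0771-BrM than in 482N1 in 32 of 36 cases and lower in 3 (median 1.22, camera adjusted p = 6.06e-10; adjusted p = 0.0557 with an estimated correlation), with Plk1 at 169 ± 8.22 against 3.23 ± 1.33 CPM and Rrm2 at 132 ± 10.4 against 3.8 ± 0.61. Amino acid stress genes were higher in 18 of 25 and lower in 6 (median 1.19, camera adjusted p = 0.00153; adjusted p = 0.42 with an estimated correlation). The stress-induced pseudokinase Trib3 had 119 ± 24.7 against 13.3 ± 2.07 CPM, the folate cycle enzyme Mthfd2 305 ± 35.3 against 51.4 ± 4.98 and the amino acid transporter Slc7a5 31.9 ± 4.96 against 2.71 ± 0.699. Vldlr, a lipoprotein receptor, had 1 count against 2453. Immediate early genes were lower in 16 and higher in 8 of 25 (median -0.89, camera adjusted p = 0.0218; adjusted p = 0.236 with an estimated correlation). Egr1 had no count in E0771-BrM, at least 789-fold lower than in 482N1, and without Egr1, a test added after the data were seen, the list was not called (camera adjusted p = 0.0856). Brain colonisation genes were higher in 5 and lower in 8 of 15 (0.2), with L1cam at 38 ± 3.04 CPM against 8 counts and the protocadherin gene Pcdh7 at 1 count against 48 ± 3.62 CPM. Cytokine genes were higher in 10 and lower in 5 of 17 (0.228), or 10 and 6 adjusted over the list alone, and the chemokine gene Ccl5 had 143 ± 12.7 CPM against 11 counts. Sterol and fatty acid genes (9 higher and 17 lower of 30, 0.483) and p53 targets (8 higher and 11 lower of 25, 0.655) were not called. Of the marker pairs, Cd68 and Egfl7 were higher and Cd14 and Flt1 lower.

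Of 11037 genes, 8622 (78.1%) differed between E0771-BrM and 482N1, 4159 higher and 4463 lower in E0771-BrM. At least 2-fold fitted changes were seen for 2022 and 2348, and at least 8-fold for 363 and 602. Of 18 lists, 8 were called, 3 higher and 5 lower, and the counts of members adjusted over the list alone differed only for the lists named above. A test against a 2-fold change, glmTreat, called 3342 genes, only the epithelial list was called with an estimated correlation, and 5 lists were called with only library B of both lines. With limma-voom the calls were lost of the lung list (camera adjusted p = 0.0912; range over the alternatives that used camera 0.00499 to 0.205) and of the immediate early list (0.112; 0.0178 to 0.236). With only library B of both lines these calls were lost as well (camera adjusted p = 0.0964 and 0.158), and so was that of the epithelial list (0.0565; 2.07e-08 to 0.0565).

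The last comparison set the breast cancer line against the melanoma line, again in different media. Measured pigment genes were lower in E0771-BrM, and the epithelial genes and most of the mesenchymal, cytokine and interferon genes were higher. All 7 melanocyte genes were lower in E0771-BrM (median -7.30, camera adjusted p = 4.99e-10; adjusted p = 0.0656 with an estimated correlation). Dct had 27 ± 21.2 CPM against 17216 ± 425 (log2 fold change -9.33 ± 0.86, edgeR quasi-likelihood adjusted p = 5.58e-05). Library B of E0771-BrM held 29 counts of Dct and libraries A and C 353 and 263, and with only library B its log2 fold change was -12.27 and the list median -8.62. Pmel had 2.3 ± 1.57 CPM against 2164 ± 101 and Tyrp1 3.01 ± 2.31 against 2038 ± 41.7. Also lower were the prostaglandin D synthase gene Ptgds, at 0.585 ± 0.406 against 1200 ± 140 CPM (-10.98 ± 0.16), and Sox11, at 10 counts against 465 ± 17.8 CPM. So were the synaptic vesicle gene Syngr1, at 1 ± 0.669 against 589 ± 55.6, the fatty acid carrier Fabp5, at 1.64 ± 1.63 against 734 ± 35.9, and Marcks, a substrate of protein kinase C, at 8 counts against 319 ± 18.4 CPM. As with Dct, libraries A and C of E0771-BrM held more of these counts than library B. In the order A, B and C they were 10, 2 and 12 for Syngr1, 27, 2 and 10 for Fabp5 and 6, 1 and 7 for Ptgds. For Marcks they were 4, 0 and 4 and for Sox11 5, 1 and 4.

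S100a6 had 2225 ± 47.9 CPM in E0771-BrM against 1.2 ± 0.411 in B16F10-BrM (log2 fold change 10.81 ± 0.12, edgeR adjusted p = 2.01e-49). Gap43, Mmp3, the lymphocyte antigen family gene Ly6e, Wfdc2, Fosl1 and alpha-fetoprotein, Afp, were at 0 in every B16F10-BrM library and at least 3320-, 2780-, 2470-, 1630-, 1620- and 1280-fold higher in E0771-BrM. All 5 epithelial genes were higher in E0771-BrM (median 9.62, or 7.87 with genes at 0 set to their bound, and 8.87 to 10.79 over the alternatives, camera adjusted p = 2.01e-06; adjusted p = 0.0557 with an estimated correlation). Krt8 had 188 ± 18.7 CPM against 2 counts, whereas Krt18 had 9 counts against 0, none of them in library B, so that its call was lost with only that library. Of 19 mesenchymal and matrix genes 13 were higher and 5 lower (median 3.79, camera adjusted p = 0.0021; adjusted p = 0.0656 with an estimated correlation). The mesenchymal transcription factor genes Prrx1 and Twist1 were at least 877- and 442-fold higher, and N-cadherin, Cdh2, was lower, at 0.536 ± 0.141 against 90.9 ± 6.65 CPM. The mammary genes Areg, Foxa1 and Gata3 were higher in E0771-BrM than in B16F10-BrM, Areg, a ligand of the EGF receptor, at least 414-fold. Erbb2 was called higher as well (edgeR adjusted p = 0.0457), but not in 8 of 19 alternatives (range 0.028 to 0.464). The lung list was not called (3 higher and 2 lower of 5, camera adjusted p = 0.708; median 0.28, mean -0.22).

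Of 17 cytokine and chemokine genes 13 were higher in E0771-BrM and 3 lower, or 14 and 3 adjusted over the list alone (median 3.50, camera adjusted p = 1.6e-06; adjusted p = 0.107 with an estimated correlation). The monocyte chemoattractant gene Ccl2 had 71.4 ± 13.5 CPM and was at least 620-fold higher than in B16F10-BrM. Ccl5 had 143 ± 12.7 against 3.15 ± 1.84 CPM (log2 fold change 5.53 ± 0.19, edgeR adjusted p = 3.5e-18) and Spp1 150 ± 12.6 against 2.18 ± 0.0413. Interferon and antigen presentation genes were higher in 21 of 24 and lower in 2 (median 2.70, camera adjusted p = 1.92e-11; adjusted p = 0.0683 with an estimated correlation). Rsad2 had 466 ± 62 against 12.4 ± 0.667 CPM (log2 fold change 5.23 ± 0.11) and Isg15 79 ± 17.9 against 1.89 ± 0.797. Of 15 brain colonisation genes 12 were higher and 3 lower (median 2.64, camera adjusted p = 0.00161; adjusted p = 0.107 with an estimated correlation). Gja1, connexin 43, was at least 546-fold higher in E0771-BrM, and Pcdh7 was lower, at 1 count against 495, a ratio of 459 (95% counting interval 81.9 to 18200). Immediate early genes were higher in 19 and lower in 5 of 25 (median 2.04, camera adjusted p = 1.15e-05; adjusted p = 0.096 with an estimated correlation). The phosphatase gene Dusp5 had 49.4 ± 5.26 CPM against 1 count and Nr4a3 1.73 ± 0.376 against 34.9 ± 3.58 CPM. Amino acid stress genes were higher in 19 and lower in 2 of 25 (median 0.82, camera adjusted p = 0.0139; adjusted p = 0.515 with an estimated correlation), with Trib3 at 119 ± 24.7 against 35.9 ± 0.91 CPM.

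No neural list was called between E0771-BrM and B16F10-BrM, and each of those tested held genes that differed in both directions. The axon guidance list had 13 genes higher and 9 lower of 24 (camera adjusted p = 0.483). Sema3a had 131 ± 5.35 CPM against 6 counts, and the semaphorin receptor Nrp1 had 6 counts, all in library B of E0771-BrM, against 36.5 ± 3.05 CPM. The channel list had 3 higher and 3 lower of 9 (0.374), with Kcnh2 at 0 in B16F10-BrM and at least 145-fold higher in E0771-BrM. The synapse organiser list had 5 higher and 5 lower of 12 (0.0968), with Cadm1 at 0.63 ± 0.58 against 273 ± 8.93 CPM and Ptprf at 4.7 ± 0.634 against 0.503 ± 0.522. The glutamate list had 6 higher and 2 lower of 8 (0.251), and the cystine transporter Slc7a11 had 37.6 ± 8.62 against 7.99 ± 1.58 CPM. The presynaptic list had 4 higher and 5 lower of 12 (0.483; median 0.18, mean -0.61), with Syt7 at 12.1 ± 0.98 CPM against 1 count and Syt4 at 39, 13 and 28 counts in libraries A, B and C of E0771-BrM against 1180 ± 1.89 CPM. The neuron and glia list had 1 higher and 6 lower of 7 (0.347), with Gap43 higher and the microtubule gene Map2 at 0 in E0771-BrM and at least 74.1-fold higher in B16F10-BrM. Of the 2 GABA genes Aldh5a1 was higher and Gabbr1 was not called, and Cd14, Cd68, Egfl7 and Flt1 were all higher in E0771-BrM.

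Cell cycle genes were not called between these lines (9 higher and 20 lower of 36, camera adjusted p = 0.414), nor were sterol and fatty acid genes (6 higher and 17 lower of 30, 0.0784) and p53 targets (6 higher and 13 lower of 25, 0.0884). Across all genes 8131 of 11037 (73.7%) differed, 4106 higher and 4025 lower in E0771-BrM, with at least 2-fold fitted changes for 1922 and 1935 and at least 8-fold for 563 and 489. Of 18 lists, 8 were called, 7 higher and 1 lower, none of which was called with an estimated correlation, and glmTreat against a 2-fold change called 2905 genes. The presynaptic list was called lower without library B of 482N1, without library C of 482N1 and without library B of E0771-BrM (camera adjusted p = 0.0145, 0.0237 and 0.021, range over the alternatives that used camera 0.0145 to 0.773). The list median was positive in each of these settings (0.18, 0.18 and 0.24), and 482N1 is not 1 of the lines compared here. The sterol list was called lower with limma-voom and with only library B of both lines (camera adjusted p = 0.0496 and 0.0423; range 0.0423 to 0.157), and the neuron and glia list with limma-voom (0.0443; range 0.0443 to 0.42).

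**Figure D2:**
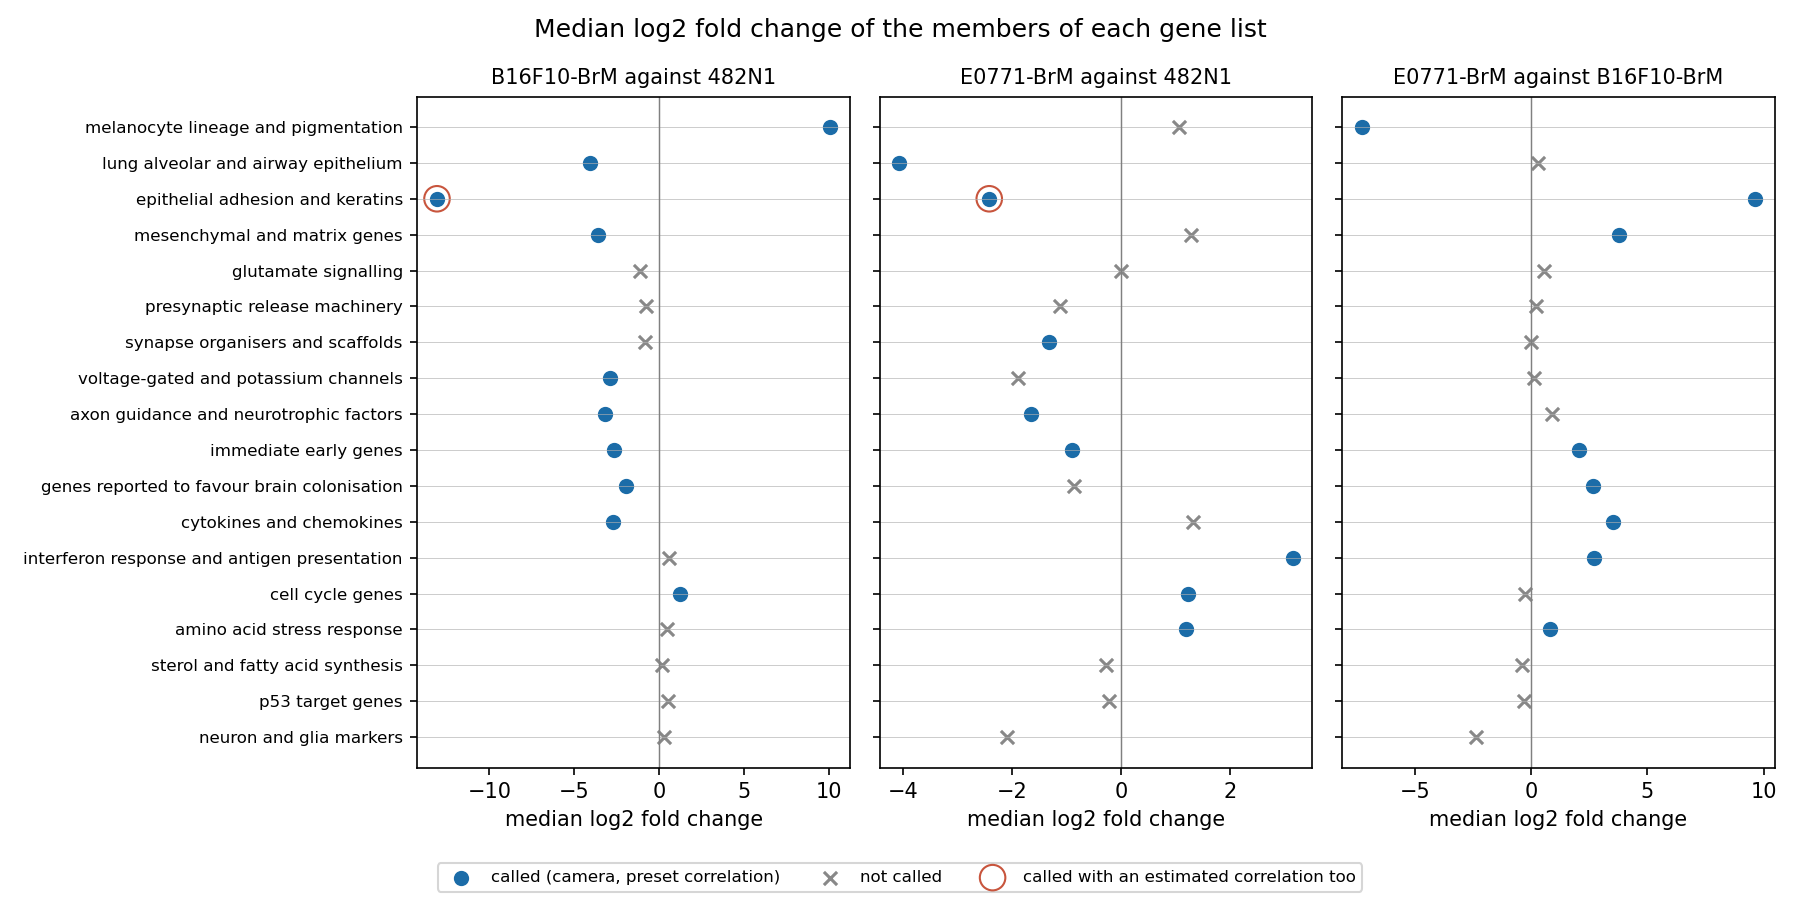
Median log2 fold change of the members of the 18 tested gene lists (x axis, a separate scale in each panel) in each of the 3 comparisons, with filled circles for lists called by camera, crosses for lists not called and an outer ring where the call held with an estimated correlation. Only the epithelial list carries a ring, in both comparisons with 482N1.

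Over all 3 lines, 10166 of 11037 genes (92.1%) differed in a joint edgeR quasi-likelihood test. In a test that a line lay above both others, 2802 genes were highest in 482N1, 2185 in B16F10-BrM and 2135 in E0771-BrM. The deposited table held few genes confined to 1 line. Of its 11046 genes, 140 had a mean below 1 CPM, before TMM scaling, in exactly 2 of the 3 lines. Only 9 were at 0 in all 6 libraries of 2 lines. How its genes were selected is not known, so the rankings below hold only among the genes in it. The genes that most set 482N1 apart were Krt18, Clu, the prostaglandin E synthase gene Ptges, Egr1, Vldlr, the integrin ligand Npnt, Onecut2 and Rps3a3, a ribosomal protein gene copy. Npnt had 257 ± 14.1 CPM against 1.89 ± 0.797 in B16F10-BrM and 1.49 ± 0.153 in E0771-BrM. Those that most set B16F10-BrM apart were Pmel, Dct, Tyrp1, Syt4, Sox11, Gxylt2, a glycosyltransferase gene, Ptgds and Sirt5. Gxylt2 had 267 ± 10.1 CPM against 8 counts in 482N1 and 14 in E0771-BrM. Those that most set E0771-BrM apart were Hspb8, Mmp3, Gap43, Lcp1, Gbp7, Rtp4, an interferon-induced chaperone gene, Apbb1ip and the adhesion gene Clmp. Rtp4 had 96.9 ± 7.8 CPM against 0.707 ± 0.117 in 482N1 and 0.96 ± 0.344 in B16F10-BrM.

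**Figure D3:**
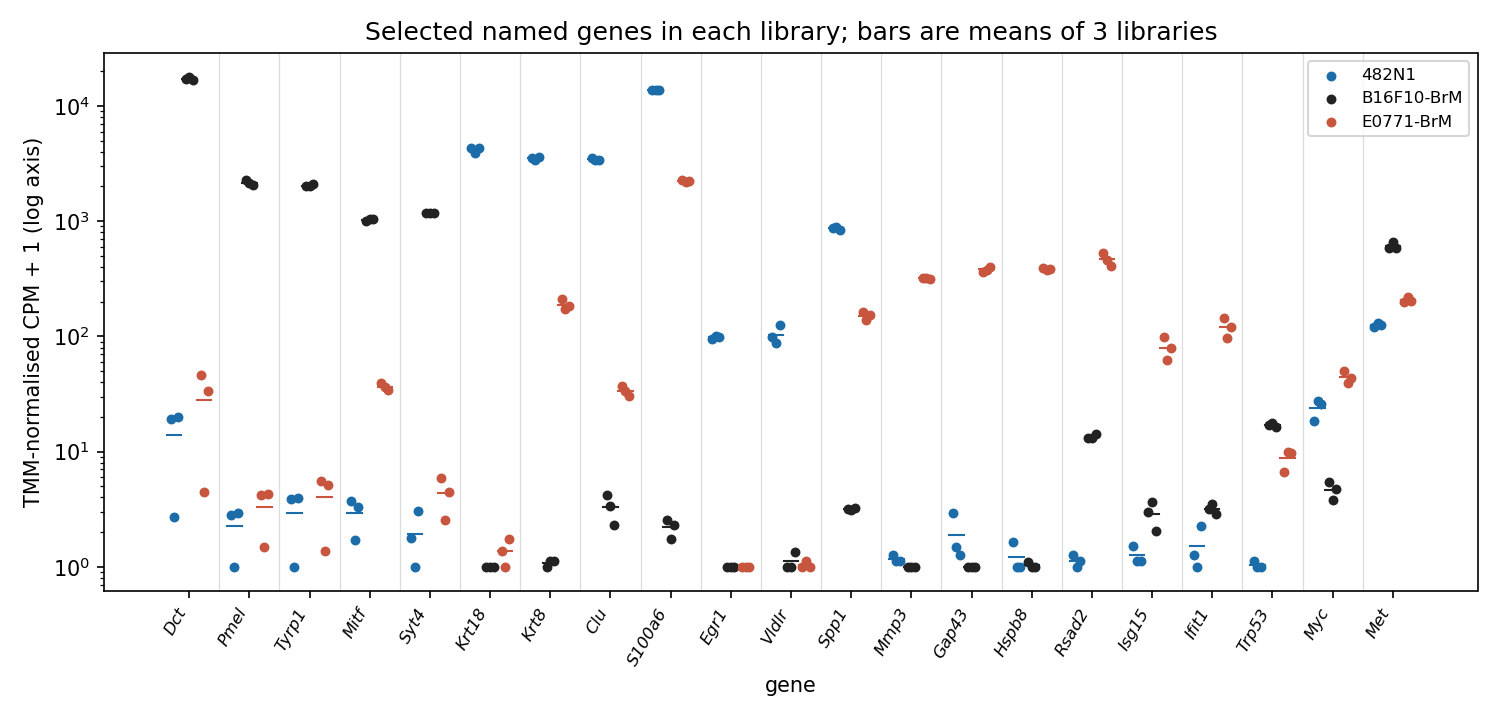
Normalised CPM plus 1 (y axis, log scale) of 21 named genes in each of the 9 libraries, with points for libraries, colours for lines and bars for the mean of 3 libraries. Egr1 is at 0 in all 6 libraries of B16F10-BrM and E0771-BrM, and Dct, Pmel and Tyrp1 are lower in library B (the middle point) of 482N1 and E0771-BrM than in libraries A and C.

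A panel of tumour genes was read in all lines. Trp53, which codes for p53, had 1 count in the 3 libraries of 482N1, against 15.9 ± 0.649 CPM in B16F10-BrM, a ratio of 381 (95% counting interval 68 to 15100), and 7.77 ± 1.79 CPM in E0771-BrM, a ratio of 187 (33.1 to 7420). The receptor gene Met was highest in B16F10-BrM, at 606 ± 43 CPM against 124 ± 5.17 in 482N1 and 205 ± 11.3 in E0771-BrM. Myc was highest in E0771-BrM, at 43.4 ± 5.76 CPM against 22.9 ± 4.93 in 482N1 and 3.66 ± 0.862 in B16F10-BrM. Egfr had 1 count in B16F10-BrM, 5.52 ± 1.61 CPM in 482N1 and 16.4 ± 1.78 in E0771-BrM. Erbb2 was lower in both other lines than in 482N1, at 23.2 ± 3.38 CPM there, 3.98 ± 0.67 in B16F10-BrM and 5.62 ± 1.09 in E0771-BrM. Braf had 31.6 ± 3.52 CPM in 482N1, 61.4 ± 6.11 in B16F10-BrM and 70.5 ± 1.55 in E0771-BrM, and the last 2 did not differ at the threshold (edgeR adjusted p = 0.0571; range over the alternatives 0.0204 to 0.235). Nf1 had 39.8 ± 1.64, 55.4 ± 1.99 and 26.1 ± 3 CPM, and Nras 147 ± 9.59, 83.1 ± 2.9 and 116 ± 2.61, each in the order 482N1, B16F10-BrM, E0771-BrM. The log2 fold changes of Hras, Rb1, Stk11 and Keap1 lay between -0.49 and 0.60 in every comparison, and neither Hras nor Rb1 was called between B16F10-BrM and 482N1 (edgeR adjusted p = 0.518 and 0.412). Calls of Erbb2, Rb1, Stk11 and Keap1 between E0771-BrM and B16F10-BrM, with log2 fold changes of 0.51, 0.44, 0.26 and -0.21, were each lost in at least 3 of 19 alternatives. Cdkn2a, Cdkn2b and the sex chromosome genes Xist, Ddx3y, Kdm5d, Eif2s3y and Uty were not in the table and are not analysed here.

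Libraries A and C of 482N1 and of E0771-BrM held more of the transcripts that are abundant in B16F10-BrM than library B did. Over 17 transcripts with at least 100 CPM in B16F10-BrM and at most 1 part in 300 of that level in 482N1, the 482N1 libraries A, B and C reached 0.13% (95% counting interval 0.117 to 0.145), 0.0323% (0.0259 to 0.0399) and 0.123% (0.11 to 0.137) of the B16F10-BrM level. Over the 17 transcripts chosen in the same way for E0771-BrM, its libraries A, B and C reached 0.25% (0.23 to 0.272), 0.029% (0.0225 to 0.0368) and 0.192% (0.174 to 0.211). These transcripts include Dct, Pmel, Tyrp1, Syt4 and Sox11. The shares are of summed counts, and Dct weighs most in them. In library A it gave 142 of 327 counts in 482N1 and 353 of 554 in E0771-BrM. With only library B of both lines, a setting chosen after the data were seen, the log2 fold change of Syt4 between E0771-BrM and B16F10-BrM was -9.55. Among named genes with a called difference, 83 of 334 fold changes moved by more than 1.5-fold when 1 library was left out.

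**Figure D4:**
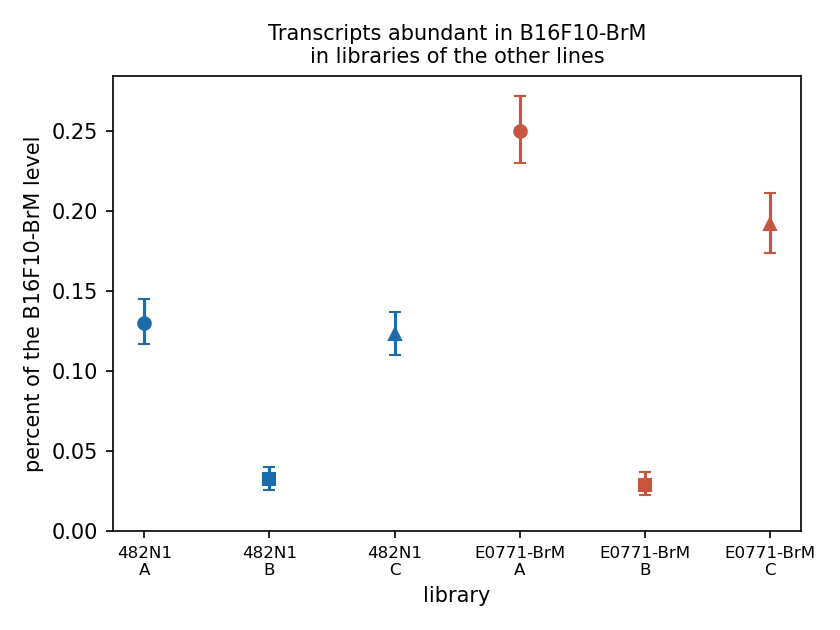
Level of transcripts abundant in B16F10-BrM in each library of 482N1 and E0771-BrM (x axis), as a percentage of their B16F10-BrM level (y axis), with 95% Poisson intervals for counting error only as bars. Library B lies at 0.0323% in 482N1 and 0.029% in E0771-BrM, below libraries A and C of the same line.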

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

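Among the settings, the removal of ribosomal RNA genes and the use of only library B of 482N1 and of E0771-BrM were chosen after the results were seen. No result that was called in the main or the alternative fit turned direction, and turns of results called in neither were not counted. Over the alternatives, 6367 of the named-gene values were called in both fits or in neither, 38 lost and 5 gained the call. For lists, 954 were called in both or in neither, 37 lost and 35 gained the call. Named genes were mostly chosen for large called differences, which favours stable calls. The counts of differing genes in the order B16F10-BrM against 482N1, E0771-BrM against 482N1 and E0771-BrM against B16F10-BrM fell to 3477 (1585 higher, 1892 lower), 3342 (1516 and 1826) and 2905 (1478 and 1427) with glmTreat against 2-fold, a stricter test by construction. With any other setting they stayed within 1.5 times, with DESeq2 at 8337, 8348 and 7873 and with only library B at 7682, 7175 and 7300. Leaving out each library gave 8233 to 8600, 8282 to 8615 and 7780 to 8191. Which side held more genes depended on the scaling. With upper-quartile factors it turned, to 4410 higher and 4151 lower in the first comparison and 3937 and 4186 in the last. In the last it also turned without ribosomal RNA genes (4058 and 4075) and with only the 2 lines compared (4063 and 4069). In the same order, the number of called lists was 1, 1 and 0 with an estimated correlation, and 17, 18 and 18 with fry, which does not compare a list with other genes. It was 6 with limma-voom in the first comparison and 5 with only library B in the second, for which the cause was not tested. Leaving out each library gave 9 to 10, 8 to 8 and 8 to 9 lists. The labels do not say that the letters A, B and C pair the libraries, and correlations of same-letter deviations from the line means, between -0.00992 and 0.0898, were all below 0.1, so the letters were not used to pair them. As hints of something shared, 1, 1 and 3 of 3 libraries correlated best with their own letter in the 3 comparisons, and libraries A and C of 482N1 and of E0771-BrM both held more B16F10-BrM transcripts than library B. With the letter as a block 8595, 8623 and 8162 genes and 10, 8 and 10 lists were called, the added lists in the last comparison being sterol synthesis (camera adjusted p = 0.0473; range 0.0423 to 0.157) and neuron and glia markers (0.0482; range 0.0443 to 0.42). Among called named genes, limma-voom moved 99 of 334 fold changes by over 1.5-fold, only library B 78, DESeq2 10 and another normalisation or filter 0. Depth limits the fold of any gene near 0 in a line.

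Other splits of the libraries into groups of the same sizes were tested as well. For genes differing among the 3 lines, 1 of 100 splits reached the real count of 10166 (highest other 2624). For genes highest in 482N1, B16F10-BrM and E0771-BrM, 1 of 100 splits did so each (2802, 2185 and 2135, highest other 851). The 1 split that reached each value was the real one. The other splits mix libraries of different lines, so the result shows that the libraries group by line. It does not show how the differences compare with variation between cultures of a line. Each pairwise comparison has 10 splits, too few for a share under 0.05, and 1 of 10 reached the real value: 8592, 8622 and 8131 genes, with 0 in the highest other, and 10, 8 and 8 lists, with 7, 5 and 7.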

Other observations

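The gene families and the shares of B16F10-BrM transcripts below, and the tests on immediate early genes and p53 targets, were chosen after the results were seen. The rule of the neighbour tests was written beforehand, but the patterns they address, Egr1 at 0 and Trp53 near 0, came from these data. Laminin genes, which code for basement membrane proteins, were lower in the melanoma line than in the lung line. All 6 measured laminin genes were lower in B16F10-BrM than in 482N1 (median log2 fold change -6.02, camera adjusted p = 8.08e-07, and adjusted p = 0.0356 with an estimated correlation). They were lower in E0771-BrM than in 482N1 in 4 of 6 cases and higher in 2 (median -3.25, camera adjusted p = 0.00455; adjusted p = 0.0791 with an estimated correlation). The laminin chain Lamb1 had a mean of 3.72 CPM in B16F10-BrM, 316 in 482N1 and 423 in E0771-BrM, and Lama5 2.25, 113 and 15.1. All 12 measured integrin genes were lower in B16F10-BrM than in 482N1 as well (median -2.66, camera adjusted p = 2.19e-06; adjusted p = 0.0791 with an estimated correlation).

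Most proteasome subunit genes were lower in 482N1 than in either other line. They were higher in B16F10-BrM in 26 of 35 cases and lower in 5 (median 0.54, camera adjusted p = 0.00128; adjusted p = 0.0791 with an estimated correlation), and higher in E0771-BrM in 33 and lower in 1 (median 0.89, camera adjusted p = 5.05e-08, and adjusted p = 0.0356 with an estimated correlation). Of 84 ribosomal protein genes, 73 were lower in B16F10-BrM than in 482N1 (median -0.68, camera adjusted p = 4.64e-06; adjusted p = 0.289 with an estimated correlation), and nuclear complex I genes were lower in E0771-BrM than in B16F10-BrM in 27 of 37 cases (median -0.55, camera adjusted p = 9.63e-04; adjusted p = 0.25 with an estimated correlation). In all, 9 families were tested, with collagen, semaphorin, serpin and mitochondrially encoded genes as the others, in 27 tests adjusted together. Hox genes were looked for as well, but fewer than 5 were measured, so they were not tested. Only laminins in B16F10-BrM against 482N1 and proteasome subunits in E0771-BrM against 482N1 were called with an estimated correlation.

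Libraries A and C of 482N1 and of E0771-BrM held more B16F10-BrM transcripts than library B. If expression of pigment genes alone by these lines were the whole source, transcripts outside the pigment list should show no such excess. In E0771-BrM these transcripts had an excess of A and C over B of 0.179% of the B16F10-BrM level (95% counting interval 0.143 to 0.214). That of the 3 pigment genes chosen, Dct, Pmel and Tyrp1, was 0.196% (0.179 to 0.213). These shares are summed over genes. The pigment value therefore rests mostly on Dct, at 17220 CPM in B16F10-BrM against 2164 for Pmel and 2038 for Tyrp1. A and C were both above B for 13 of 14 transcripts outside the list. The excess was therefore not confined to pigment genes, and B16F10-BrM material in these libraries could account for it. Expression by the line itself is not excluded. All these transcripts were picked from the same data as abundant in B16F10-BrM and low in the line, which caps their shares. Those outside the list may also be expressed together with pigment genes. In 482N1 the excess outside the list was 0.0733% (0.0372 to 0.109), and that of the 5 pigment genes chosen 0.1% (0.0889 to 0.112). However, A and C were both above B for only 7 of 12 transcripts outside the list. The interval also leaves out variation between libraries, so that the source in 482N1 stays open as well. In the other directions the excess was 0.0761% (0.0293 to 0.123) for E0771-BrM transcripts in 482N1, where library C overlapped library B, 0.0301% (0.0147 to 0.0454) for 482N1 transcripts in E0771-BrM, some of which, such as Cadm1, Marcks and Sox4, are also abundant in B16F10-BrM, 0.00364% (-0.00346 to 0.0107) for 482N1 transcripts in B16F10-BrM and -0.019% (-0.0435 to 0.00563) for E0771-BrM transcripts in B16F10-BrM.

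Egr1 had no count in B16F10-BrM or E0771-BrM. A deletion of every copy that reaches the nearest tested genes is excluded, since these genes had counts. Kdm3b on one side had 210 counts in B16F10-BrM and 179 in E0771-BrM, and Etf1 on the other 5312 and 5533. A deletion of only some copies that reaches these genes could not be tested. A line with no immediate early transcripts is excluded too, since of the other 24 tested immediate early genes only 3 in B16F10-BrM and 0 in E0771-BrM had 3 or fewer counts. That count does not exclude lower immediate early expression as a whole. Of 25 such genes with Egr1, 21 were lower and 3 higher in B16F10-BrM than in 482N1, and 16 and 8 in E0771-BrM. A loss that stops short of Kdm3b and Etf1, or silencing of Egr1, may also explain the absence, and neither could be tested in these data.

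Trp53 had 1 count in the 3 libraries of 482N1. A deletion of every copy that reaches the nearest tested genes is excluded, since Wrap53 had 246 counts and Sat2 332 in that line. One that reaches them on only some copies could not be tested. Loss of p53 activity could lower its target genes in 482N1, but the p53 target list was not called against B16F10-BrM (median log2 fold change 0.52) or E0771-BrM (-0.21), which decides nothing. Whether the line carries a lesion within Trp53 needs its DNA sequence.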
